A study of Mus musculus with 2 samples.

How the data were processed

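Heart RNA of 2 animals was measured by total RNA sequencing. Per the labels' protocols, libraries were made with a directional RNA library kit from 300 ng of RNA with ERCC spike-ins for libraries depleted of ribosomal RNA. For each library 3 kinds of table were deposited. Per the deposited description files, the assembly was mm10 and the annotation GENCODE M21; a gene table and a transcript table were derived from transcriptome alignments, and the other transcript table from a FASTQ file of reads. The aligner and the quantification tools are not given in the sources used here, although the column names are those that RSEM and kallisto write.

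Per the file headers, the gene table and the first transcript table hold expected counts, that is, estimated counts that need not be whole. Per the file headers they also hold TPM and FPKM, and the deposited TPM sum to 1000000 over all features of a library. In the first transcript table, the isoform percent (IsoPct) is, per the file headers, each transcript's share of its gene. The FASTQ-derived table holds estimated counts and TPM, per the file headers. Posterior mean TPM and credibility bounds were deposited too; the interval level is not given in the sources used here. The bounds hold the posterior mean in over 99% of genes with counts and the plain TPM in 92.7% and 92.5%. The deposited effective length of a gene with 1 transcript was in the median its length less 100 bases, so TPM of short RNAs rests on few usable positions.

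Reads were assigned to the mm10 reference, which is the C57BL/6J genome, although the animals carry a CAST/EiJ genome as well. Reads of the CAST/EiJ allele that differ from the reference may be assigned less well, and no allele-specific values were analysed. All 55536 mouse gene identifiers matched the GENCODE M21 annotation. The tables also list 96 ERCC features, 1 phiX feature and 26248 features named only by a number. A symbol with several gene records takes the record of the highest mean TPM.

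Depth was 42223411 and 40553237 expected counts in the alignment-derived tables and 43782858 and 41468698 estimated counts in the FASTQ-derived ones. A protein-coding gene near 1 TPM had a median of 73.6 counts in replicate 1 and 76.0 in replicate 2. Floors cover counting error only. Credibility intervals can be wider than counting error: Gm14440, with 317.67 counts and 2.88 TPM in replicate 1, had bounds of 0.17 and 8.08 TPM. Neither covers variation between animals, and reads without molecular identifiers are not independent molecules. A count of 0 was given the limit of 3 counts.

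Both animals form 1 group, so no groups were compared and no test between groups was made. The labels give each library its own animal number and biological replicate number, and the same donor identifier for both. That identifier was read here as naming the strain, so n = 2 animals rests on the animal numbers. A gene was called expressed at 1 TPM or more in both animals. Paralogue ratios used log2(TPM + 0.01) and list medians log2(TPM + 1). For the difference between the animals, log2 ratios of TPM + 0.1 were centred on the median of genes with a mean of 1 TPM or more and at least 20 expected counts over both libraries. Such ratios understate differences of low genes. A list of at least 3 compared genes was set against 10000 random lists of the same size drawn from the same 10 bins of mean expression. Count ratios added 0.5 to each count. Isoform shares were computed from the TPM of each transcript table.

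Before the data were examined, 39 gene lists, 25 paralogue pairs, 22 isoform genes, the thresholds and the rule for named genes were fixed. The rule names both members of every pair and the 10 most abundant protein-coding genes. It also names the 4 highest members of each list and members under 1 TPM in both animals, the 10 protein-coding genes with the largest ratio between the animals in each direction, and the isoform genes. The last parts are the 10 protein-coding genes farthest apart between the transcript tables, the 5 most abundant lncRNA genes, and the sex-linked genes. Other names, among them Gm28661, Gm29216, Gm10925, Slc4a1 and the list members named for a 2-fold difference, were chosen after their values were seen.

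The comparison of the animals was tested on simulated data: Poisson counts drawn from the real means and library sizes, with 200 of 11856 compared genes changed. Of the genes changed 1.5-fold, 0 of 50 passed the 2-fold rule, and of those changed 3-fold, 4-fold and 8-fold, 50 of 50 each. Among 11656 unchanged genes, 20 passed. Of 100 simulated lists of 12 genes without a shift, 3 lay outside the central 95% of a smaller set of random lists, and of 100 lists shifted by 0.4 on the log2 scale, 100 did. The simulated counts had no variation between animals, no shared regulation within a list and no error of read assignment. These rates therefore cover counting error only and do not give the rate of false calls in the real libraries.

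Alternatives tried were other thresholds, pseudocounts and filters, FPKM, expected counts, the FASTQ-derived table, scaling by edgeR's TMM factors of the expected counts rounded to whole numbers or by the spike-ins, removal of trends with GC content and length in 20 bins each, and leaving out each replicate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with R 4.3.3 and edgeR 4.0.16 for the TMM factors.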

Results

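Total RNA was sequenced from the hearts of 2 adult female mice of the B6CASTF1/J strain, the F1 hybrid of C57BL/6J and CAST/EiJ parents, at an age of 8 to 10 months. The series has 1 group and no treatment, so the data describe the RNA of the hybrid heart and how far 2 animals differ. Replicate 1 is the animal numbered 1 in the labels and replicate 2 the animal numbered 3. The gene tables held 42223411 expected counts for replicate 1 and 40553237 for replicate 2. Values are means ± SD over the 2 animals (n = 2) unless an animal is named. An exact sign-flip test over 2 animals cannot give a two-sided p below 0.5, so no p-value is given.

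The label of the sex was borne out by the sex-linked genes. Xist, the noncoding RNA of the inactive X chromosome, stood at 14.0 ± 3.10 TPM (transcripts per 1000000). The Y-linked genes Ddx3y and Eif2s3y stood at 0.030 ± 0.028 and 0.010 ± 0.014 TPM, and Kdm5d and Uty had no count in either library. A count of 0 allows up to 0.0711 counts per 1000000 in replicate 1 and 0.0740 in replicate 2, by counting error only.

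Of 55536 annotated mouse genes, 11590 (20.9%) reached 1 TPM in both animals, among them 10721 of 22028 protein-coding genes and 131 of 5854 lincRNA genes. At a threshold of 5 TPM the number was 7062. Across the 11590 genes the TPM of the 2 animals correlated with a Pearson r of 0.990 on the log2(TPM + 1) scale and a Spearman rho of 0.984; genes are not independent replicates. A chi-square of the counts, 39.0 per degree of freedom over 15305 genes, shows only that the files are not repeat deposits of 1 library; that the animals are separate rests on the animal numbers in the labels.

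RNA of the mitochondrial genome took 38.1% ± 4.09 of all TPM. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 held 22.7% ± 2.90 and the 13 mitochondrial mRNAs 15.5% ± 1.19. By the labels' protocols the libraries were depleted of ribosomal RNA. Shares of TPM are therefore those of the libraries and may differ from those of heart RNA. The most abundant protein-coding genes were mt-Co1 and mt-Co3, subunits of cytochrome c oxidase, at 35282 ± 671 and 32382 ± 165 TPM, followed by mt-Atp6 at 17625 ± 3354, mt-Cytb at 15994 ± 1376 and mt-Nd1 at 10996 ± 655 TPM. In the transcript table derived from FASTQ files without the alignments mt-Co1 led too, but mt-Co3 stood at 13735 ± 12.4 TPM, below mt-Atp6 at 30166 ± 2099 and mt-Cytb at 16840 ± 1586 TPM. By contrast mt-Co2, another subunit of the same enzyme, was listed at 585 ± 53.8 TPM. The pseudogene Gm28661 (chromosome 1, 24614885 to 24615565, minus strand, mm10) was listed at 31575 ± 1403 TPM, and its neighbours Gm29216 and Gm10925 at 20061 ± 1014 and 11724 ± 824 TPM. These 3 genes, singled out after their values were seen, held 6.34% ± 0.04 of the TPM; all but a few of their 31-base words also occur in mitochondrial transcripts, so their values and those of mt-Co1, mt-Co2, mt-Atp6 and mt-Atp8 are uncertain, as is that of mt-Co3, on which the tables differ. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, held 15.1% ± 0.55 of TPM with identical counts on each copy. As a share of expected counts, which is not divided by length, the pair held 2.46% ± 0.01 and the 3 pseudogenes 2.69% ± 0.09.

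Nuclear protein-coding genes held 35.6% ± 3.22 of TPM, and the 22 sarcomere genes 4.64% ± 0.40. Of expected counts they held 57.7% ± 4.38 and 9.73% ± 0.84. Myl2, the ventricular regulatory myosin light chain (chromosome 5, 122100951 to 122113472, plus strand), led with 9141 ± 522 TPM. Myh6, the adult myosin heavy chain of the mouse heart (chromosome 14, 54941921 to 54966927, minus strand), had 8288 ± 745 TPM, and Mb, the oxygen store myoglobin (chromosome 15, 77015487 to 77050670, minus strand), 7236 ± 565 TPM. Cardiac actin, Actc1, stood at 4691 ± 1054 TPM and cardiac troponin I, Tnni3, at 4030 ± 247 TPM. All 22 sarcomere genes exceeded 1 TPM in both animals, with a median of 774 ± 69.0 TPM. Of 14 calcium handling genes, 13 did, with a median of 137 ± 15.4 TPM. The calcium pump Atp2a2 had 4570 ± 513 TPM, its inhibitor phospholamban (Pln) 3003 ± 266 and the release channel Ryr2 400 ± 63.4; Fkbp1b, at 0.10 ± 0.00 TPM, was the exception. Among 12 cardiac transcription factors the median was 25.5 ± 1.90 TPM, with Mef2a at 46.7 ± 6.56 and Gata4 at 39.7 ± 1.02 TPM, while the embryonic factors Isl1 and Hand1 stood at 0.005 ± 0.007 TPM and at 0 counts.

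Genes of oxidative energy supply were high. The 21 nuclear genes of the respiratory chain had a median of 748 ± 55.9 TPM, led by Atp5b at 3411 ± 233 TPM. The 23 genes of fatty acid oxidation had a median of 305 ± 11.7 TPM, led by the fatty acid carrier Fabp3 at 2230 ± 285 and by Hadhb at 888 ± 95.5 TPM. The 18 genes of the TCA cycle had a median of 261 ± 20.8 and the 19 genes of glucose uptake and glycolysis one of 210 ± 16.2 TPM, with Gapdh at 1933 ± 84.0 TPM. All members of these 4 lists were expressed in both animals. On the log2(TPM + 1) scale the median of fatty acid oxidation exceeded that of glycolysis by 0.54 ± 0.06, in both animals. This difference depends on the members listed. The glycolysis list holds lower paralogues such as Hk1, Pgam1 and Eno1, at 38.7, 38.7 and 45.4 TPM. The fatty acid oxidation list holds Cpt1a, at 19.5 TPM. The difference was not computed without such members. The 12 regulators of fuel choice had a median of 69.5 ± 6.96 TPM. Among them Oxct1, an enzyme of ketone body use, had 460 ± 56.6 TPM.

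**Figure D1:**
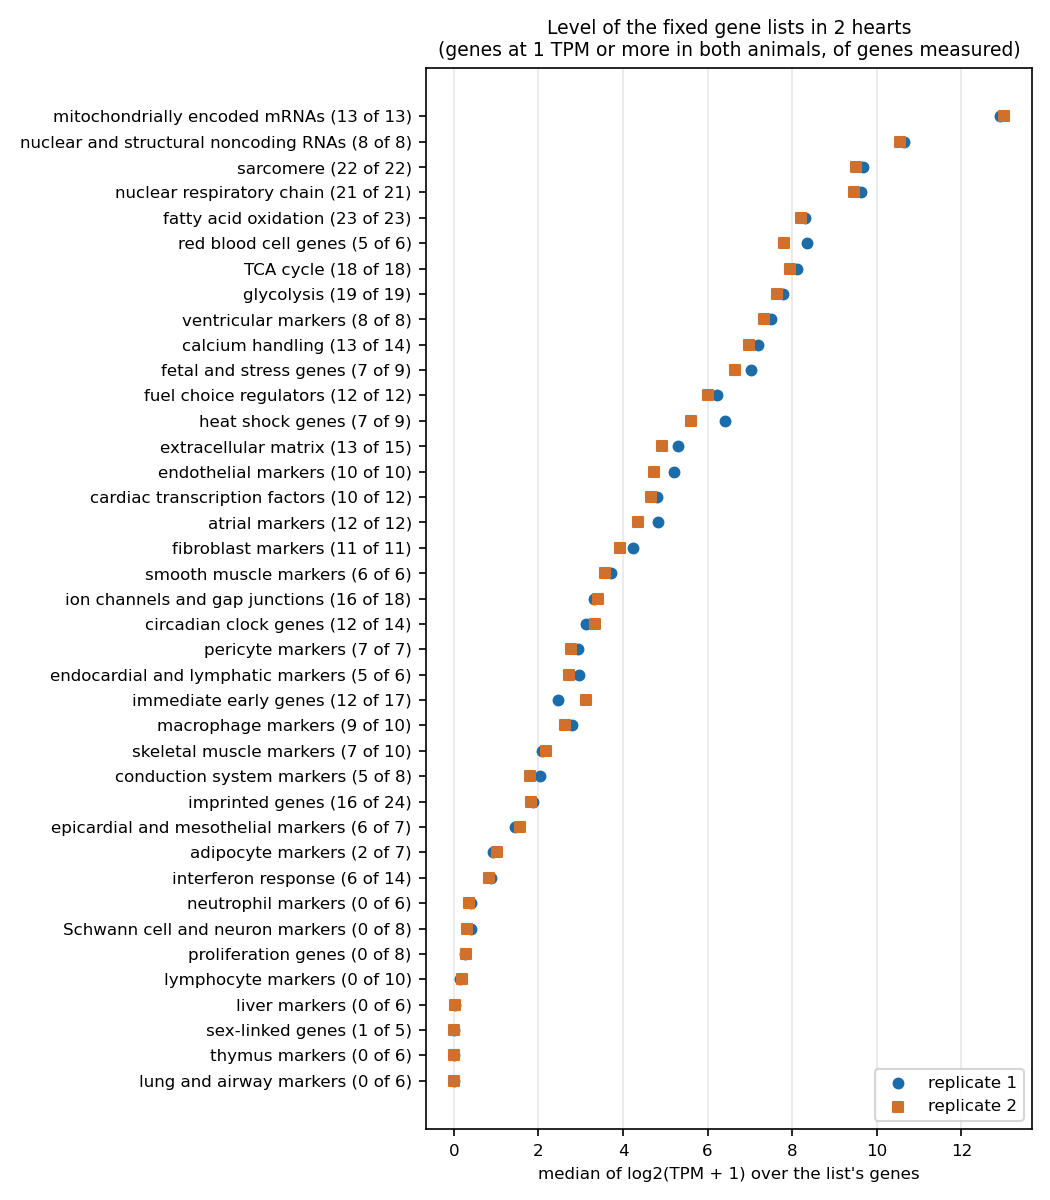
Median of log2(TPM + 1) over each of the 39 gene lists (x axis) in replicate 1 (blue circles) and replicate 2 (orange squares), with the number of genes at 1 TPM or more in both animals. Mitochondrial mRNAs, structural noncoding RNAs, sarcomere and respiratory chain genes lie highest, and markers of lymphocytes, liver, lung and thymus lie near 0.

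Each of the 25 paralogue pairs was one-sided, and in each the gene named first was higher. One-sided means a log2 ratio of at least 1 with the same sign in both animals and above 3 times their SD. The pairs and their order were fixed beforehand, with heart or muscle forms such as Actc1, Tnni3 and Cpt1b first. The count therefore describes the chosen pairs and is no test. Myh6 exceeded Myh7, the slow myosin heavy chain, 12.1-fold (log2 ratio 3.60 ± 0.13). In the FASTQ-derived table the log2 ratio was 2.59 ± 0.19. Cardiac actin Actc1 exceeded skeletal Acta1 by 5.36 ± 0.05 on the log2 scale, and the ventricular light chain Myl2 exceeded atrial Myl7 47.2-fold (5.56 ± 0.43). Tnni3 exceeded the fetal troponin I gene Tnni1, at 0.675 ± 0.276 TPM, by 12.58 ± 0.51 on the log2 scale. For the calcium pumps Atp2a2 over Atp2a1 the difference was 10.31 ± 0.23 and for the release channels Ryr2 over Ryr1 10.18 ± 0.50. Among the enzymes, muscle Cpt1b exceeded Cpt1a, the liver form of the carnitine palmitoyltransferase that admits fatty acids to mitochondria, 11.6-fold. The insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 29.4-fold, and Ldhb exceeded Ldha 4.25-fold. The smallest ratios were those of Cox7a1 over Cox7a2, 3.23-fold, and of Hk2 over Hk1, 3.75-fold.

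**Figure D2:**
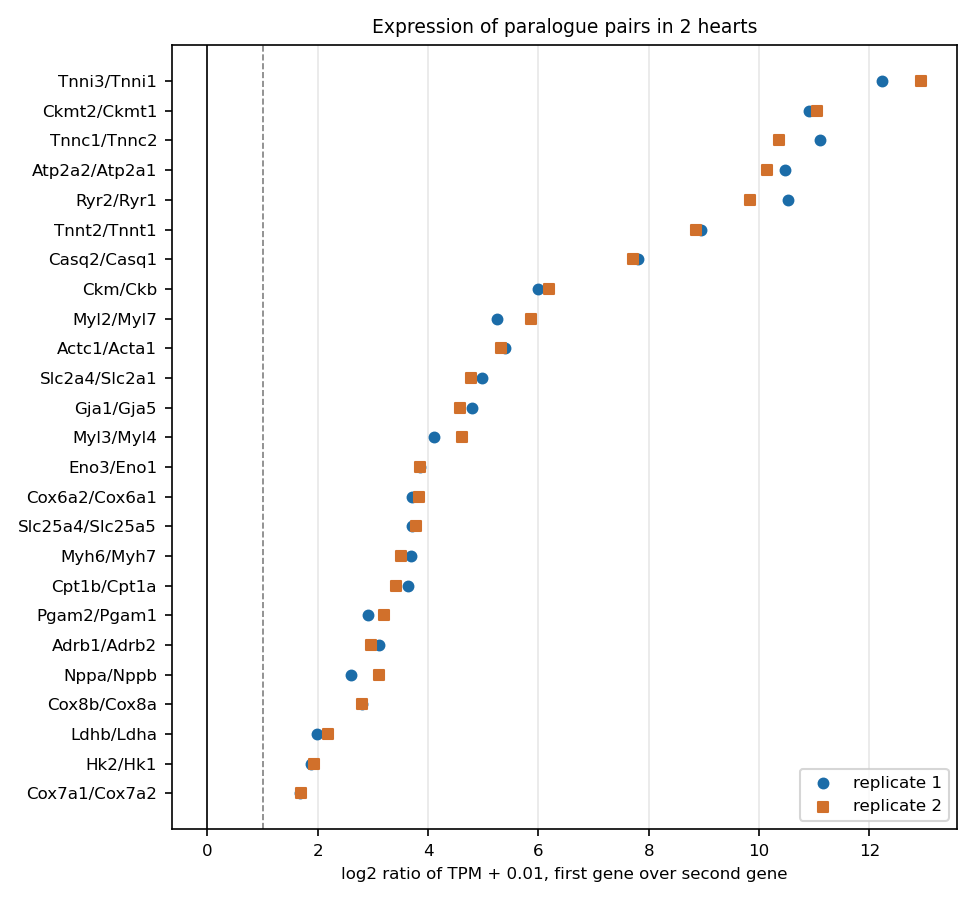
Log2 ratio of TPM + 0.01 of the first over the second gene of 25 paralogue pairs (x axis) in replicate 1 (blue circles) and replicate 2 (orange squares); the dashed line marks a log2 ratio of 1. All points lie to the right of it, from Cox7a1/Cox7a2 at 1.69 to Tnni3/Tnni1 at 12.58 on average.

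Markers of other cell types lay below the sarcomere genes, except that the order of red blood cell and sarcomere genes depended on the members counted. The 6 red blood cell genes had a median of 434 ± 130 TPM, with the globin gene Hbb-bs at 1034 ± 321 TPM, and the sarcomere median exceeded theirs by 1.52 ± 0.26 on the log2 scale. The difference depended on 1 low member, Slc4a1, at 0.535 ± 0.658 TPM: with only members at 1 TPM or more in both animals it was 0.0362 ± 0.323. The order then turned in replicate 1, where the median red blood cell gene, Hba-a2, had 939.5 TPM against a sarcomere median of 823 TPM, but not in replicate 2, with 604 against 725 TPM. All 10 endothelial markers were expressed, with a median of 31.3 ± 6.98 TPM and the fatty acid carrier Fabp4 at 198 ± 5.90 TPM. All 11 fibroblast markers were expressed too, with a median of 16.1 ± 2.70 TPM and Dcn at 113 ± 12.3 TPM. Medians were 11.9 ± 0.24 TPM for 6 smooth muscle markers, led by Smtn, 6.22 ± 0.59 for 7 pericyte markers, led by Abcc9, and 5.91 ± 0.60 for 10 macrophage markers, led by Lyz2 at 30.7 ± 5.32 TPM. For every marker list these are levels in whole heart RNA. Which cells made a marker, such as Abcc9, was not measured, and no share of cells follows. None of the 10 lymphocyte, 6 neutrophil and 8 proliferation genes reached 1 TPM in both animals; Mki67, a marker of dividing cells, had 0.290 ± 0.057 TPM. The liver, lung and thymus lists were likewise without an expressed member, with Alb at 0.010 ± 0.014 and Sftpc at 0.065 ± 0.035 TPM. Of the chamber markers, 8 ventricular genes had a median of 171 ± 14.6 TPM and 12 atrial genes 23.4 ± 5.44 TPM. Atrial natriuretic peptide, Nppa, stood at 547 ± 217 TPM.

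Several groups of genes differed between the animals as a set. Immediate early genes, which cells induce within minutes of a stimulus, were higher in replicate 2: 11 of 14 compared, with a median log2 ratio of replicate 2 over replicate 1 of 0.49. Fos had 0.88 TPM in replicate 1 and 8.11 TPM in replicate 2 (log2 ratio 3.25), and Fosb 0.43 and 3.71 TPM (3.03), whereas Jun and Dusp1 differed by 0.03 and 0.16. Clock genes were higher in replicate 2 in 8 of 12 (median 0.20), with Dbp at 0.71 and Nr1d1 at -0.28; in the other transcript table the median was 0.07, inside the range of random lists. By these centred ratios mitochondrial mRNAs were higher in 12 of 13 (0.36), and epicardial and mesothelial markers in 5 of 6 (0.50). In uncentred TPM mt-Co1, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd6 were lower in replicate 2, and the other mitochondrial mRNAs were higher. Mitochondrial ribosomal RNAs took 20.6% of TPM in replicate 1 and 24.7% in replicate 2, and nuclear protein-coding genes 37.8% and 33.3%. Lower in replicate 2 were heat shock genes in 7 of 9 (-0.46), with Hspa8 at -0.53, and red blood cell genes in 5 of 5 (-0.43). So were fetal and stress genes in 6 of 7 (-0.40), with Nppb at -1.16, and atrial markers in 11 of 12 (-0.30), with Nppa at -0.65 and Myl7 at -0.55. Nppa is on both of these lists. Extracellular matrix genes were lower in 10 of 13 (-0.16) and endothelial markers in 8 of 10 (-0.15); the matrix median was -0.11 in the other transcript table, inside the range of random lists.

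These 10 were the lists, out of 31 compared, outside the central 95% of 10000 random lists matched on mean expression. From independent lists of unrelated genes with no difference, 1.55 would be expected outside. Genes of a list that vary together put more lists outside, so the 1.55 does not measure an excess. All 10 were also among 13 outside by expected counts. The 3 others were fibroblast markers at -0.13, smooth muscle markers at 0.20 (-0.03 by TPM) and skeletal muscle markers at 0.26. In the FASTQ-derived table fibroblast and skeletal muscle markers were outside too, at -0.17 and 0.30. After removal of GC content and length trends, conduction system markers were outside as well, at 0.27, against 0.25 and inside before. Sarcomere, fatty acid oxidation, glycolysis, TCA cycle and nuclear respiratory chain genes lay inside, at 0.01, -0.03, 0.01, 0.02 and 0.03. With 1 library per animal the differences have no replicate check, and the percentiles describe these libraries only. The epicardial, red blood cell and endothelial markers moved between the same 2 libraries as the immediate early and atrial genes.

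**Figure D3:**
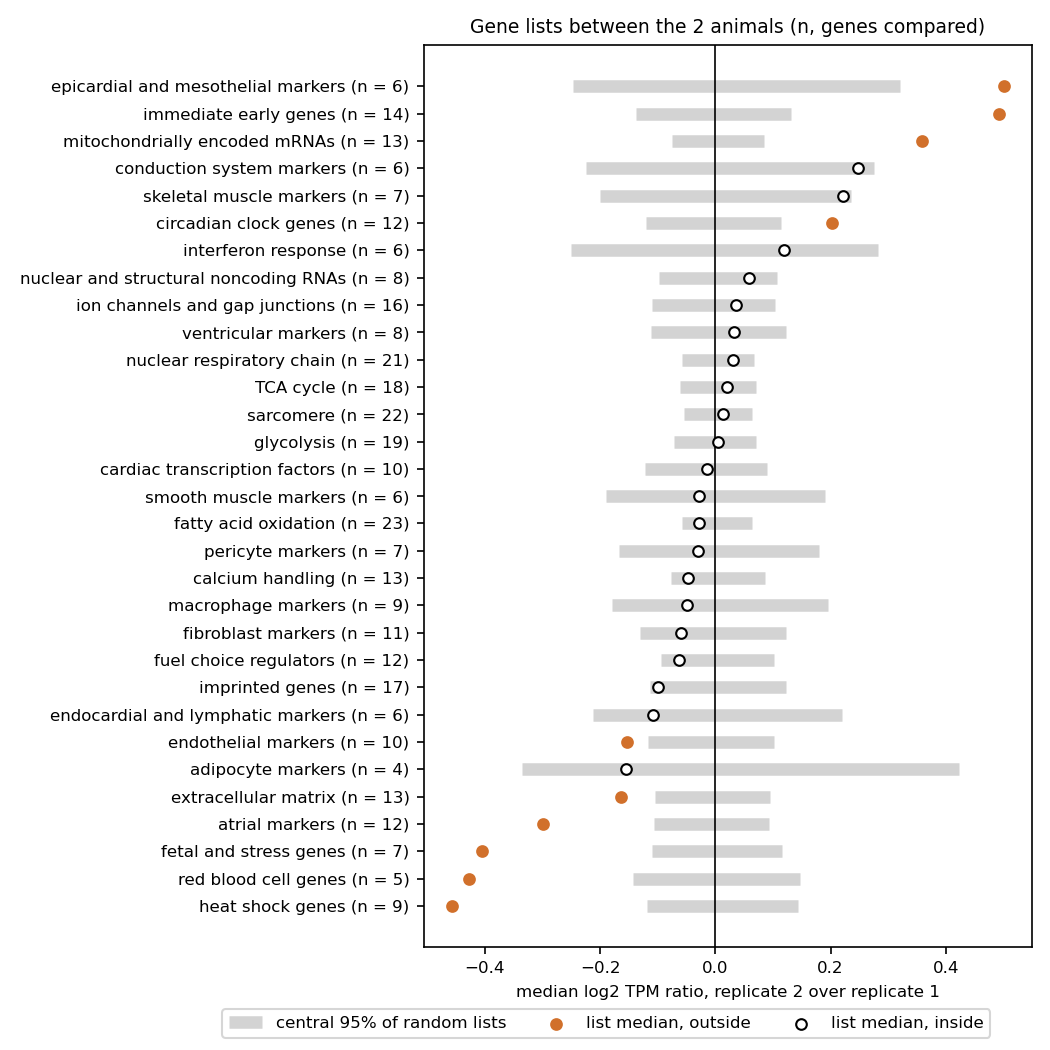
Median log2 TPM ratio of replicate 2 over replicate 1 (x axis) for 31 gene lists; filled points lie outside and open points inside the central 95% of 10000 random lists (grey bars). Epicardial and immediate early genes lie farthest to the right, at 0.50 and 0.49, and heat shock genes farthest to the left, at -0.46.

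For single genes, 168 of 11876 compared were 2-fold or more apart, 84 in each direction, and 73.6% lay within 1.2-fold. The credibility intervals of 74 of the 168 did not overlap, and 58 were 2-fold apart in the same direction by TPM, by expected counts and in the other transcript table. With no scaling beyond TPM, 51 genes were higher and 131 lower in replicate 2, as the median log2 ratio was then -0.18. Besides Fos and Fosb, the protein-coding genes with the largest ratios that both tables bore out included Mt2, the metal-binding metallothionein, at 12.7 and 47.2 TPM (2.07), and Snai3 at 1.01 and 4.90 TPM (2.35). In the other direction they included the chemokine Ccl9 at 3.50 and 0.57 TPM (-2.24), which was under 2-fold by counts, and 3110009E18Rik at 2.85 and 0.74 TPM (-1.63). Hist1h4n, a histone gene with 6.53 TPM in replicate 1 and 0 counts in replicate 2, had 1.24 and 0 TPM in the FASTQ-derived table. Some other large TPM ratios were not seen in that table. The ribosomal protein gene Mrpl23, at 9.22 and 0.46 TPM, stood there at 53.8 and 54.5 TPM, and Gm9803, at 6.23 TPM and 0 counts, at 5.18 and 5.37 TPM. Zfp969, 1700047I17Rik2 and Gm14440 were close to 0 there in both animals, and for Zc3h11a that table gave the opposite direction; the cause was not tested.

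Of 22 genes chosen for their isoforms, 16 had the same main isoform in both transcript tables. Tpm1-205 held 97.2% ± 0.03 of the tropomyosin gene's TPM in the alignment-derived table and 64.4% ± 3.00 in the other. Ryr2-201 held 85.6% ± 0.14 and 89.0% ± 0.27, Ldb3-203 69.3% ± 0.07 and 68.9% ± 0.50, and Ttn-201, an isoform of the giant spring protein titin, 40.0% ± 0.96 and 45.5% ± 0.90. For cardiac troponin T the tables named different isoforms: Tnnt2-211 held 73.7% ± 0.04 in the first and 2.76% ± 2.93 in the second, where Tnnt2-212 held 52.5% ± 6.09. Cacna1c, Slc8a1, Pdlim5 and Nexn were also among those without a shared main isoform. In the alignment-derived table the 2 animals shared the main isoform in 19 of 22 genes, the exceptions being Mef2c, Bin1 and Fn1.

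**Figure D4:**
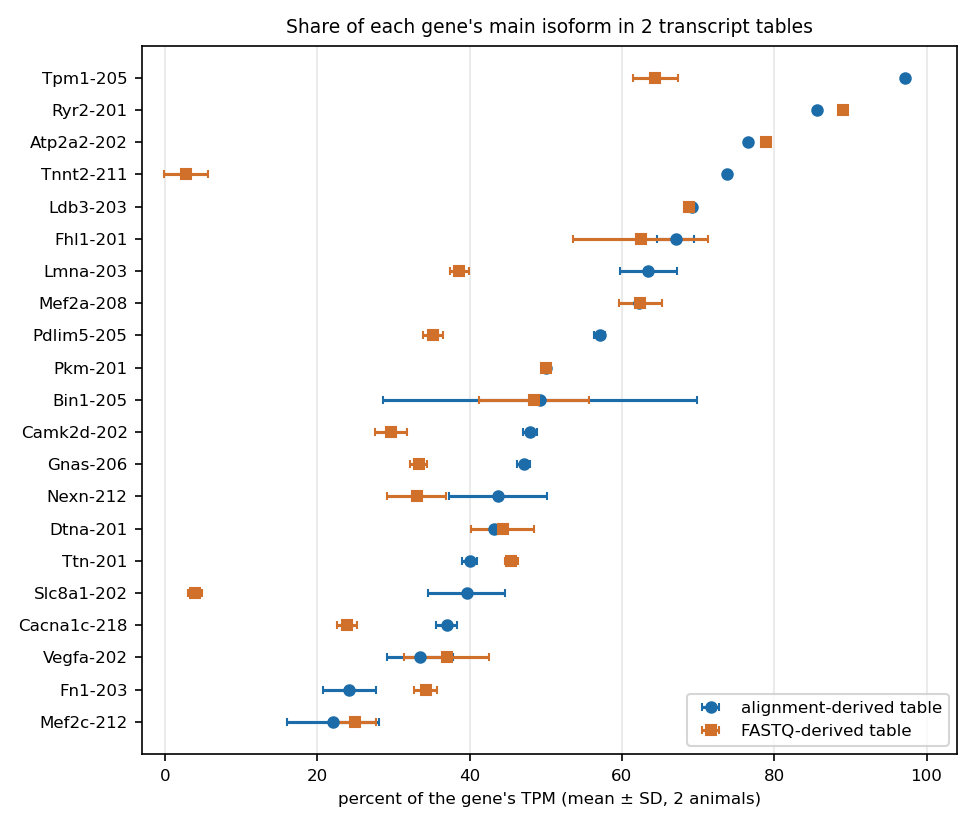
Percent of a gene's TPM in the isoform that is highest in the alignment-derived table (x axis, mean ± SD of 2 animals) in that table (blue circles) and in the FASTQ-derived table (orange squares), for 21 of the genes. The tables lie close for Ldb3-203 (69.3% and 68.9%) and far apart for Tnnt2-211 (73.7% and 2.76%).

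Summed to genes, the 2 transcript tables were 2-fold or more apart in both animals for 516 of 12072 genes (4.27%), 197 higher and 319 lower in the FASTQ-derived table; 105 of these were among 11021 protein-coding genes. Spearman's rho across genes was 0.911 in replicate 1 and 0.909 in replicate 2. The farthest protein-coding gene was mt-Atp8, which overlaps mt-Atp6 on the mitochondrial genome, at 5686 ± 2644 and 2.12 ± 0.32 TPM. Snurf, which shares its locus with Snrpn, had 100 ± 9.36 TPM in the first table and was listed at 0 in the second.

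The ERCC spike-ins, synthetic RNAs added in known amounts, held 0.278% ± 0.029 of TPM. Over the 25 spike-ins with at least 100 counts the median log2 ratio of replicate 2 over replicate 1 was -0.21, with an SD of 0.14 across spike-ins. For mouse genes the median was -0.18.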

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

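Outside the comparisons, a signal above the 3 counts that a count of 0 allows appeared in 2 kinds of feature. The phiX feature, a bacteriophage genome often added to sequencing runs as a control, held 76.0 counts in replicate 1 and 44.0 in replicate 2. The 26248 features named only by a number held 3.87 expected counts in replicate 2 and 1.95, below that limit, in replicate 1. No explanation was tested for either.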

How the results depend on the processing

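After seeing the data, 10 alternatives were added: all those of the list and table counts, and expected counts, trend removal, the tables' close genes and the pseudogene and ribosomal RNA classes for the others. Of 67 alternatives, 53 stayed within 1.5 times the count or within 1 SD of the value, and none reversed the direction of a mean over the animals. Part of this was fixed in advance. With 2 animals, the value of either lies within 1 SD of their mean. FPKM is TPM times a constant per library, so it hardly changes a share or ratio. A pseudocount of 1 is the main setting of the list differences. These alternatives are no check of those values. The moves of Myh6 over Myh7 and of the list means were not traced, and the cause was not tested. A pseudocount of 1 shrinks the ratios of low genes, and a share of counts is not divided by length. The others follow from which genes or totals enter or from the threshold. Genes at 1 TPM or more became 7062 at 5 TPM. Genes 2-fold apart between the animals became 1884 without a filter, 51 at a mean TPM of 5 or more, 79 with a pseudocount of 1 and 90 among genes on which the 2 transcript tables were within 2-fold; leaving out an animal leaves no difference to compute. The mitochondrial mRNA share became 30.4% of protein-coding TPM, 11.6% of counts, 21.8% with the 3 pseudogenes and 24.9% without mitochondrial ribosomal RNAs, Rn7s1 and Rn7s2. The log2 ratio of Myh6 over Myh7 became 2.59 in the FASTQ-derived table. Fatty acid oxidation minus glycolysis became 0.61 with means, and sarcomere minus the highest other cell type list 3.22 with means and 0.0362 with expressed members only. Genes 2-fold apart between the tables became 261 at a mean TPM of 5 or more. All 25 paralogue pairs stayed one-sided in each of 6 alternatives. Those with FPKM or with 1 animal were all but fixed in advance. FPKM hardly changes a ratio, and the rule already asks for a log2 ratio of 1 in each animal. Leaving out each animal in turn gave 11870 to 12022 expressed genes, a mitochondrial mRNA share of 14.6% to 16.3% and a spike-in share of 0.258% to 0.298%. The log2 ratio of Myh6 over Myh7 was then 3.50 to 3.69. On the log2 scale fatty acid oxidation minus glycolysis was 0.50 to 0.58 and sarcomere minus red blood cells 1.34 to 1.70. Each time 15 genes had a shared main isoform. With 1 animal a pair was judged without an SD. No paired analysis was possible because the series has 1 group. Genes near 1 TPM rest on about 73.6 to 76.0 counts, and with 1 library per animal the difference between the animals has no test.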

Other observations

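The tests of the immediate early pattern, the comparison of the pseudogenes between tables and the trend removal for atrial markers were chosen after the results were seen.

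Of the 24 genes of the imprinted list, 16 were present in the adult heart, with a list median of 2.64 ± 0.12 TPM. Imprinting means expression from 1 parental allele. Whether these genes, Gnas included, were so expressed in this heart was not measured. Gnas led with 447 ± 47.4 TPM, followed by Igf2r at 42.1 ± 4.66, Snrpn at 34.6 ± 5.78 and Igf2, a growth factor better known from fetal tissue, at 25.7 ± 3.23 TPM. Peg10, Nnat, Kcnq1ot1, Dlk1, Mirg, Rtl1 and Phlda2 stayed under 1 TPM. Of 18 ion channel and gap junction genes, 16 were expressed (median 9.51 ± 0.31 TPM), led by the gap junction gene Gja1 at 156 ± 19.6 TPM. Conduction system markers were expressed in 5 of 8 (median 2.91 ± 0.62 TPM) and endocardial and lymphatic markers in 5 of 6 (6.74 ± 0.77 TPM), led by Prox1 at 20.1 ± 2.58 TPM. Skeletal muscle markers reached 1 TPM in 7 of 10 (3.41 ± 0.21 TPM); Myod1, the skeletal muscle regulator, had 0.010 ± 0.014 TPM. Adipocyte markers did so in 2 of 7 (0.970 ± 0.085 TPM), interferon response genes in 6 of 14 (0.823 ± 0.053 TPM), and Schwann cell and neuron markers in 0 of 8 (0.290 ± 0.064 TPM).

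Medians of the other lists were 114 ± 21.7 TPM for fetal and stress genes, 66.0 ± 25.2 for heat shock genes, 33.9 ± 6.22 for extracellular matrix, 8.52 ± 1.04 for clock genes, 6.11 ± 2.27 for immediate early genes and 1.83 ± 0.16 for epicardial and mesothelial markers. For nuclear and structural noncoding RNAs the median was 1840 ± 64.1 TPM and for mitochondrial mRNAs 8012 ± 425 TPM. By annotated biotype, the most abundant lncRNA genes were Gm26917 at 5560 ± 62.4, Gm42418 at 1091 ± 48.8, Rmrp at 839 ± 55.6, Malat1 at 787 ± 165 and Gm15543 at 131 ± 12.6 TPM. Gm26917 and Gm42418 lie next to each other on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788). Which RNA their reads come from was not tested. Rmrp is also on the list of structural noncoding RNAs. Among list members 2-fold apart between the animals, Per1, a clock gene, had 12.3 TPM in replicate 1 and 28.1 TPM in replicate 2, Egr1 1.90 and 4.51, and Nr4a1 2.59 and 6.39. Lower in replicate 2 were Ccn2 with 39.5 and 16.9 TPM, Angptl4 with 2.61 and 1.00, and Hspa1a with 1.78 and 0.55, besides Nppb.

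Nnt, the mitochondrial transhydrogenase gene that carries a deletion of several exons in C57BL/6J mice, has 2 overlapping gene records on chromosome 13 (119335448 to 119408997 and 119335528 to 119408952, mm10). The alignment-derived table placed all counts on the first, at 247 ± 21.9 TPM, and listed the second at 0. In the FASTQ-derived table the first had 112 ± 17.0 TPM and the second 124 ± 0.02 TPM. Their sums, 247 ± 21.9 and 236 ± 17.1 TPM, differed by less than the spread between animals, so a reader of the second record alone would see either no Nnt or a substantial level. No allele-specific value was analysed here.

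The chromosome 1 pseudogenes Gm28661, Gm29216 and Gm10925 ranked among the 11 most abundant genes. Reads shared with mitochondrial genes are a candidate source: at least 97.2% of the 31-base words of each occur in mitochondrial transcripts, those of Gm28661 in mt-Co2. A product of the alignment-derived table alone is argued against for Gm28661, which kept 97.2% of its TPM in the FASTQ-derived table (99.0% in replicate 1 and 95.4% in replicate 2). All its words occur in mt-Co2, so its level in both tables does not show which of the 2 genes its reads came from. A product of the alignment-derived table alone stays open for Gm29216, which kept 23.4% (14.1% and 33.4%). For Gm10925 it is a candidate, since only 0.101% was kept (0.140% and 0.0593%), although all its words are shared and which table is right was not tested. Summed, mt-Co2 and Gm28661 had 32161 ± 1349 TPM, against 585 ± 53.8 for mt-Co2 alone. No biological explanation was tested.

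Immediate early genes were higher in replicate 2 by a median log2 ratio of 0.49. The length correction of TPM is argued against, since the median was 0.50 by expected counts, and a trend with GC content or length is too, since it was 0.47 after their removal, outside the central 95% of random lists in both cases. More RNA of another cell type stays open: epicardial and mesothelial markers were higher in replicate 2 by a median of 0.50, outside random lists. Their highest member, Upk3b, had 5.85 ± 1.36 TPM, and whether that layer carries the immediate early genes was not measured. With 1 group, the design names no biological explanation, and the time or handling of each dissection is not given in the sources used here.

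Atrial markers were lower in replicate 2 by a median log2 ratio of -0.30, while ventricular markers differed by 0.03. A smaller share of atrial tissue in that library is a candidate explanation. Of 8 further atrial-enriched genes written down before the test, 7 could be compared and their median was -0.22, below the central 95% of random lists (-0.17 to 0.17); 5 of the 7 were lower, and Kcnk3 and Angpt1 were not. A trend with GC content or length is argued against, since the list's median was -0.30 after removal. No biological explanation was tested, and a lower expression of these genes in the same amount of tissue stays open.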
